A study of Mus musculus with 22 samples.

How the data were processed

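RNA counts per gene were analysed for 22 libraries of sorted mouse cells: endothelial cells and motor neurons of wild-type and Plxnd1 knockout embryos (3 libraries per group, as deposited), and endothelial cells of the spinal cord and of the meninges (5 libraries each). The deposited values are raw counts, which per the file headers the authors made with featureCounts 1.6.4, summing exons per gene name. Per the labels, reads had been trimmed with Trimmomatic 0.39 and aligned with STAR to mm10 (GRCm38) with the GENCODE M22 basic annotation. Per the file headers, the 12 files of the knockout series were counted without regard to strand as single-end reads, and the 10 regional files with a reverse strand setting as read pairs, although the labels name a stranded kit. Levels were therefore not tested between the 2 series. No option for reads with several alignments was set, so such reads are left out of the counts, and genes with near-identical copies can lose reads.

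The file of wild-type endothelial batch 2 was left out because it is identical to that of knockout batch 1 in all 55376 genes, and its header names the library of the latter. Which wild-type library belongs in its place is not known. The other 21 libraries were used. Embryos were pooled by genotype, and batch numbers in the labels pair the libraries. As a check of the pairing, log2 levels centred within groups correlated at r = 0.516 and 0.44 in the endothelial pairs, at 0.359, 0.413 and 0.379 in the motor neuron pairs, and at -0.273, -0.032, 0.303, 0.169 and 0.038 in the spinal and meningeal pairs. Crossing the numbers 1 and 2 of the regional series gave 0.211 and 0.331.

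The tests, gene lists, comparisons, alternatives and the rule for naming genes were fixed before the data were examined, except where stated. Each comparison used the edgeR 4.0.16 quasi-likelihood F-test in R 4.3.3, with TMM scaling, filterByExpr at a minimum count of 10 and a Benjamini-Hochberg adjusted p of 0.05. The knockout was tested within each cell type, with 3 residual degrees of freedom in endothelial cells and 4 in motor neurons. The cell types and the interaction were tested in 1 fit of the 11 libraries, and the spinal and meningeal libraries 5 against 5. A last fit compared the regional difference between ventral and whole cord. Batch as a block, called pairing in the report, had been set as an alternative, with 1 residual degree of freedom in endothelial cells and 2 in motor neurons. It became the basis of the gene-level account of the knockouts after the unpaired test had called 0 and 2 genes. Levels are CPM, counts divided by the TMM-scaled library size, and log2 levels used a prior count of 2.

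The 33 gene lists (13 of cell types and 20 of pathways or quality) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at a correlation estimated from the residuals, and with fry, which tests a list against no change instead of against other genes. Their p-values were adjusted over the lists. With few residual degrees of freedom the estimated correlation is itself uncertain, and members share reads and cells, so a preset correlation gives small p-values. For each list the members that rose, fell or did not pass were counted, adjusted over all genes and over the list alone. The tests were tested on simulated data with 200 changed genes and a list of 20 genes shifted by 0.5, before they were run on the counts. At a fold of 2, unpaired edgeR recovered 51 % of the changed genes in the endothelial knockout, 80 % in the motor neuron knockout, 58 % between cell types, 35 % in the interaction, 78 % between regions and 23 % in the dissection test. It also made 17 false calls in the endothelial and 18 in the motor neuron knockout, and DESeq2 made 61 and 42. The shares hold for data with 200 changed genes. In the real counts unpaired edgeR did not call Plxnd1 itself (log2 fold changes -3.21 and -2.97), so the shares may overstate its power.

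Other tools and settings were DESeq2 1.42.0, edgeR scaling by ratios to the median library, no filter, a filter at 5 CPM, glmTreat at a fold of 1.5, batch as a block, and leaving out each library. For processed pseudogenes, 10251 annotated sequences were searched with blastn 2.17.0+ against transcripts of other genes, at 90 % identity over at least 150 bases, and 4887 had a parent gene. Regional signatures held the 200 genes of smallest p in each direction with an absolute log2 fold change over 1, and distances to Plxnd1 were limited to 20 Mb. Genes were named by a rule: Plxnd1 and genes fixed for the question; the 10 rising and 10 falling genes with the largest changes, or the 5 with the smallest p where too few passed; and the members of lists with the smallest p. Gapdh, Ldhb, Rn7sk and the barrier genes that fell in the regional comparison lie outside the rule and were chosen after their values were seen, as were the genes of the closing section that the report does not name. Genes of the Y chromosome and Xist were tested but are not reported by library. Some single-gene results of the motor neuron comparison are not reported here.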

Results

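Gene expression was measured by sequencing polyadenylated RNA of sorted cells from mid-gestation mouse embryos. Motor neurons carried a GFP reporter of Isl1, a transcription factor gene of these neurons, and endothelial cells, which line the vessels, carried a Cherry reporter of Kdr, the main receptor for the growth factor VEGF. In the knockout series both cell types came from spinal cord taken with its meninges, in 3 batches of wild-type embryos and 3 of embryos lacking Plxnd1, a receptor for class 3 semaphorins. In the regional series wild-type endothelial cells came from the cord tissue or from the meninges, with 5 libraries of each. Batches 1 to 3 of the cord held the ventral part and batches 4 and 5 the whole cord. The endothelial library labelled wild type, batch 2, held the same count as knockout batch 1 for each of 55376 genes, whereas the next closest of 231 pairs of libraries differed in 24532 genes. This library was left out, so 21 of 22 libraries were used and wild-type endothelial cells had n = 2. Totals were 20680902 to 27035395 counts in the 11 used libraries of the knockout series and 15685784 to 21493255 in the 10 regional ones. Embryos had been pooled by genotype and the number of embryos was not given in the sources used here, so p-values measure the spread between these libraries.

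Plxnd1 was lower in each knockout library than in each wild-type library of the same cell type. Endothelial levels were 178 and 213 CPM (counts scaled by library size) in wild type and 15.5, 18.6 and 29.1 CPM in the knockout. Motor neurons had 5.07, 7.80 and 12.1 CPM in wild type and 0.644, 0.769 and 1.77 CPM in the knockout. The knockout means were 10.8 % of wild type in endothelial cells and 12.8 % in motor neurons. The labels do not say which part of the gene was deleted, and counts cover all exons. The library left out, labelled wild type, had 727 Plxnd1 counts against 4856 and 5997 in the other wild-type endothelial libraries. In the unpaired edgeR test the log2 fold change was -3.21 ± 0.26 (SE; adjusted p = 0.161) in endothelial cells and -2.97 ± 0.46 (adjusted p = 0.80) in motor neurons. With wild-type and knockout libraries paired by batch it fell by 3.04 ± 0.11 (edgeR adjusted p = 5.5e-15; 2.7e-79 to 1 over the alternatives) and by 3.0 ± 0.20 (adjusted p = 1.4e-04; 5.3e-26 to 1). In the regional series, which was counted with other settings so that levels are not compared with those above, Plxnd1 was at 611 ± 139 CPM in spinal and 387 ± 131 CPM in meningeal endothelial cells (SD, n = 5 each).

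**Figure D1:**
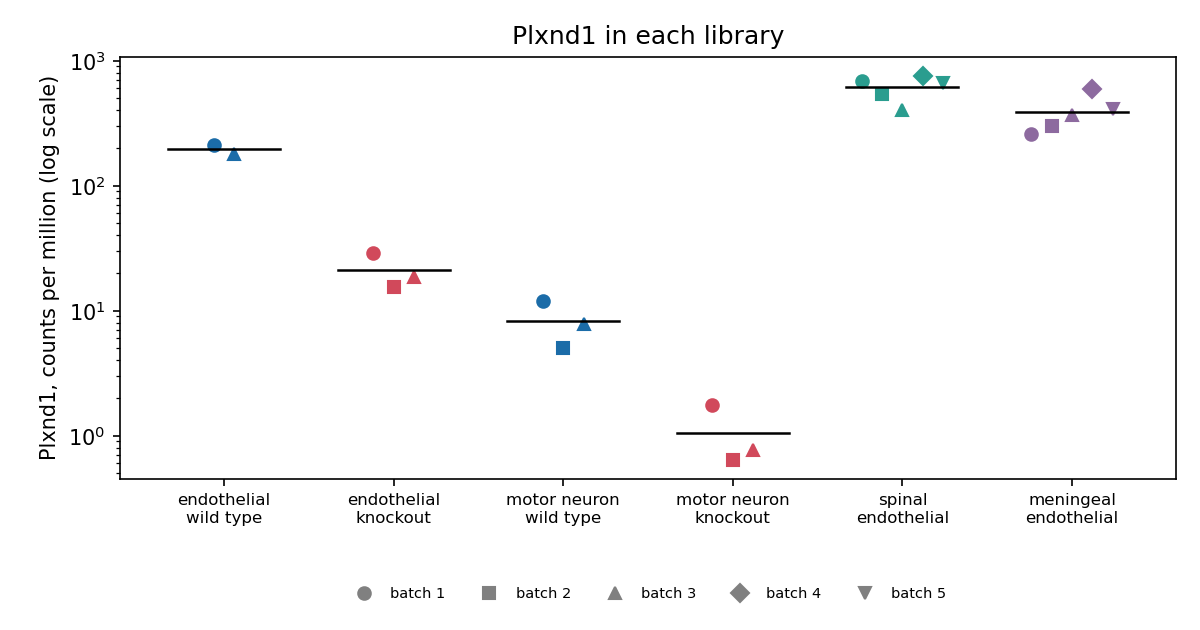
Plxnd1 in CPM on a log axis, one symbol per library with its shape giving the batch, and a black line at each group's mean. The 3 knockout libraries lie below every wild-type library of the same cell type, at 15.5 to 29.1 in endothelial cells and 0.644 to 1.77 in motor neurons.

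The first comparison asked what endothelial cells express differently without Plxnd1. Of the fixed lists, glycolysis was higher in knockout endothelial libraries in both pairs of batches, with 5 of 19 members passing, while 3 of 22 barrier and 2 of 20 endothelial genes fell. With an estimated correlation camera called none of the 33 lists in either fit (adjusted p = 0.109 for glycolysis, the smallest, and 0.582 with pairing). Ldha, which makes lactate, rose from 164 ± 8.33 CPM (SD, n = 2) to 262 ± 27.7 CPM (n = 3), a log2 fold change of 0.62 ± 0.09 (SE) with libraries paired by batch. Cldn5, the main claudin of vessel tight junctions, fell from 121 ± 36.4 to 63.1 ± 23.2 CPM (-0.70 ± 0.09), and Slc38a5, an amino acid transporter, fell from 26.5 ± 3.48 to 9.27 ± 2.03 CPM (-1.35 ± 0.14). Lars2, a mitochondrial tRNA ligase gene, rose from 78.7 ± 7.04 to 154 ± 12.8 CPM (0.92 ± 0.09), with an unpaired p among the smallest that did not pass (edgeR adjusted p = 0.558). Lars2 was also very high in knockout motor neuron batch 1, a library with unusual RNA described below. A property of the libraries can therefore not be told apart from a change in the cells. In the edgeR test paired by batch, 139 genes rose and 41 fell of 18209 tested at an adjusted p under 0.05. Of the fixed list of 5 sex-linked genes, 4 fell and 1 did not pass. Among those that fell, Ddx3y and Kdm5d were higher in 1 of 2 pairs, so the pairs disagreed on them. Wild-type Ddx3y was at 43.1 ± 61.0 CPM, and its unpaired change was 0.41 ± 2.07. Without Y genes and Xist 177 genes were called. Without pairing, as the test had been set, edgeR called 0 genes, with 431 genes at an unadjusted p under 0.05 and 910 expected by chance. DESeq2 called 28 higher and 6 lower, all 34 of them among the paired calls. The count with pairing hung on the fit: a paired edgeR fit of all knockout-series libraries called 11 higher and 4 lower, and DESeq2 with pairing 42 and 13. The paired fit has 1 residual degree of freedom from 2 pairs and borrows its spread from all genes; batch 2 has no partner. Pairing had been planned as an alternative before the data were examined, and it was put first here only after the unpaired test had called no gene. Below, "rose" and "fell" refer to the paired test for the knockouts, with paired log2 fold changes and their SE.

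Of 19 tested members of the list for glycolysis and hypoxia, 5 rose, none fell and 14 did not pass; adjusted over the list alone, 10 rose. The 5 were glycolytic enzymes: Ldha, Eno1 (52.2 ± 12.8 to 78.8 ± 5.06 CPM, 0.68 ± 0.11), Aldoa (0.53 ± 0.09), Pfkl (0.50 ± 0.09) and Tpi1 (0.47 ± 0.09), the last of which lies 8.84 Mb from Plxnd1 on chromosome 6. Vegfa, a hypoxia-induced ligand, and the glucose transporter Slc2a1 did not pass, at -0.08 ± 0.09 and -0.07 ± 0.09. The list's median was 0.35 without pairing, with 16 of 19 members above 0 (camera adjusted p = 4.2e-17; adjusted p = 0.109 with an estimated correlation). The median difference was 0.264 in the pair of batch 1 and 0.436 in that of batch 3. For 8 members, processed copies exist elsewhere in the genome, 39 in all, and reads can be divided between gene and copy. Cartilage markers moved with the list: 4 of 9 tested members of the muscle and cartilage list rose, among them the cartilage collagen Col2a1 (240 ± 88.8 to 411 ± 76.0 CPM, 0.74 ± 0.10), its regulator Sox9 (0.74 ± 0.10), Col9a1 (0.46 ± 0.09) and Acan (2.23 ± 0.49). The list's unpaired median was 0.65 (camera adjusted p = 1.2e-08; adjusted p = 0.158 with an estimated correlation).

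**Figure D2:**
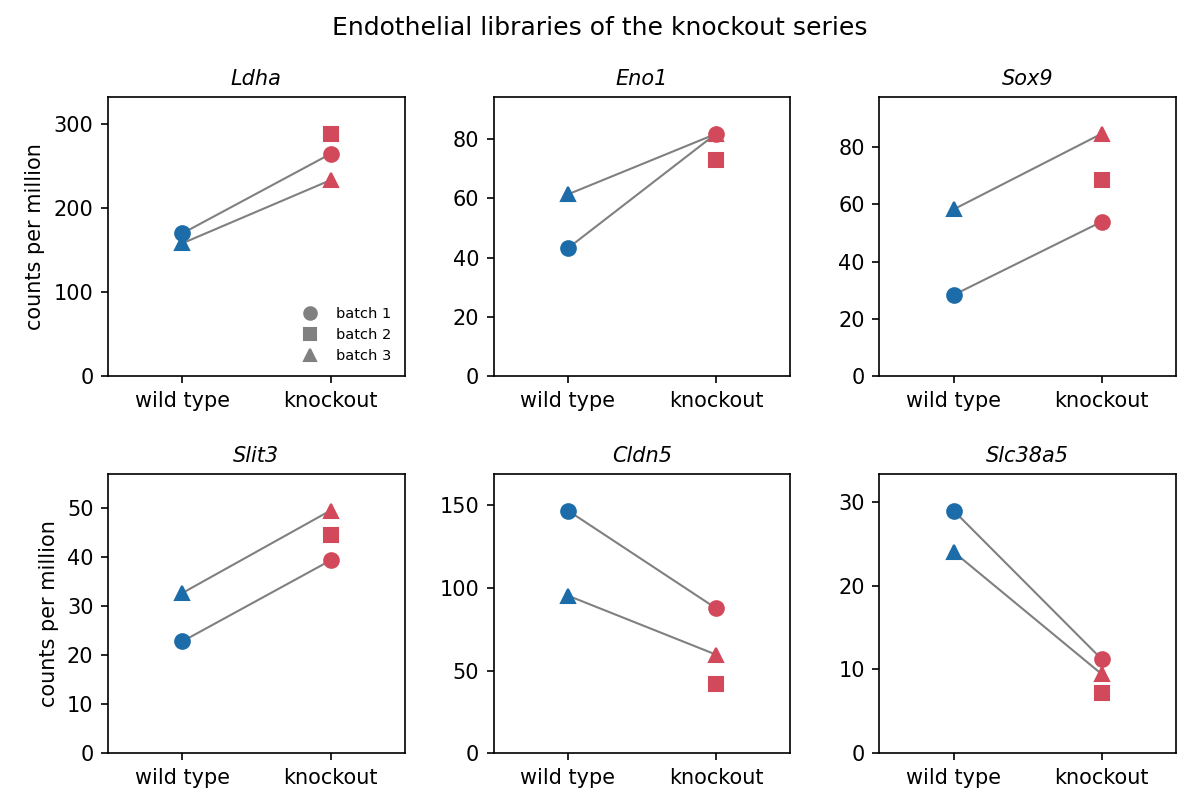
CPM values of 6 genes in the endothelial libraries of the knockout series, with symbols for the batches and grey lines joining libraries of the same batch. Ldha, Eno1, Sox9 and Slit3 lie higher in the knockout in both joined pairs, and Cldn5 and Slc38a5 lower.

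Of 22 barrier genes, 3 fell (Slc38a5, Cldn5 and the thyroid hormone transporter Slco1c1, -0.89 ± 0.18, also on chromosome 6), none rose and 19 did not pass; adjusted over the list alone, 6 fell and 1 rose. The lipid transporter Mfsd2a was at 36.4 ± 5.96 and 30.8 ± 7.46 CPM (-0.05 ± 0.11) and did not pass. The barrier list's unpaired median was -0.26 (camera adjusted p = 1.8e-07; adjusted p = 0.773 with an estimated correlation) and -0.03 without wild-type batch 1, where the call ended (camera adjusted p = 0.2). Among 20 endothelial markers, Cldn5 and the vessel-secreted factor Egfl7 (87.9 ± 29.9 to 55.1 ± 21.1 CPM, -0.51 ± 0.10) fell and 18 did not pass, Kdr (-0.19 ± 0.10) and its relative Flt1 (0.21 ± 0.10) included. That list's unpaired median was -0.33 (camera adjusted p = 1.6e-06; adjusted p = 0.905 with an estimated correlation), the paired one -0.10, and without wild-type batch 1 it was 0.02 (adjusted p = 0.665). Without knockout batch 2 it was -0.12 (camera adjusted p = 0.0597). The pairs disagreed on it, with a median of -0.246 in batch 1 (2 of 20 genes higher) and 0.049 in batch 3 (11 of 20), while the barrier list was at -0.249 and -0.079. Aplnr, the apelin receptor of veins, fell (123 ± 34.6 to 65.5 ± 17.0 CPM, -0.67 ± 0.11). Vwf, an endothelial clotting factor gene 9.64 Mb from Plxnd1, rose (0.86 ± 0.13).

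Of 29 guidance genes outside the semaphorins, 6 rose, none fell and 23 did not pass, and 12 rose when adjusted over the list alone. They included the repulsive ligands Slit2 (0.48 ± 0.09) and Slit3 (27.7 ± 6.96 to 44.4 ± 5.08 CPM, 0.71 ± 0.11), the ligand Ntn1 (0.64 ± 0.13) and the netrin receptor Unc5c (0.68 ± 0.11). The unpaired median was 0.10 (camera adjusted p = 2.9e-04; adjusted p = 0.905 with an estimated correlation); it was 0.05 without wild-type batch 1 and -0.02 without knockout batch 3, where the calls ended (adjusted p = 0.601 and 0.449). Of 31 semaphorin and plexin genes, 3 rose, among them Sema3a (31.0 ± 5.89 to 48.9 ± 12.8 CPM, 0.57 ± 0.12) and the semaphorin receptor Plxna2 (0.41 ± 0.09), only Plxnd1 fell and 27 did not pass. The Plxnd1 ligands did not pass: Sema3e was at 10.5 ± 0.035 and 15.2 ± 5.82 CPM (0.27 ± 0.19) and Sema3c at 96.3 ± 4.74 and 96.4 ± 9.04 CPM (-0.02 ± 0.10). Genes with large changes included Zpld1, which encodes a membrane protein (8.26 ± 0.833 to 30.9 ± 7.67 CPM, 1.7 ± 0.14), the activin subunit gene Inhba (1.99 ± 0.28), the matrix glycoprotein gene Thbs1 (31.9 ± 4.33 to 89.8 ± 25.1 CPM, 1.44 ± 0.16), Alx4, a homeobox gene of mesenchyme (1.51 ± 0.20), and Prrt4 on chromosome 6 (2.0 ± 0.19), all higher. Slc6a13, a GABA transporter of fibroblasts, and Pianp lie 5.34 and 9.02 Mb from Plxnd1 and fell (-0.51 ± 0.09 and -2.25 ± 0.22). Without wild-type batch 1, unpaired edgeR called 1 gene, the pseudogene Gm13394 (-7.77, adjusted p = 0.00895; 2.6e-19 to 1 over its alternatives).

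The second comparison asked what motor neurons express differently without Plxnd1. No member of the glycolysis or motor neuron lists passed by itself; both lists had medians above 0, and neither was called with an estimated correlation. Of 19 members of the list for glycolysis and hypoxia, 18 were above 0 with a median of 0.21 (camera adjusted p = 4.6e-06; adjusted p = 0.565 with an estimated correlation). None passed in either fit, and 7 rose in the paired fit adjusted over the list alone. Members included the enzyme gene Eno1 (41.6 ± 3.17 to 57.7 ± 8.52 CPM, SD, n = 3 each; unpaired log2 fold change 0.47 ± 0.12) and the VEGF ligand Vegfa (108 ± 10 to 140 ± 15.4 CPM; 0.37 ± 0.11), both higher in 3 of 3 batches.

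Of 16 motor neuron markers, 15 were above 0 and none passed by itself, with a median of 0.21 (camera adjusted p = 0.040; adjusted p = 0.901 with an estimated correlation). This call ended without wild-type batch 1 (median 0.16), wild-type batch 3 (0.01), knockout batch 1 (0.15) or knockout batch 2 (-0.04). Chat, for acetylcholine synthesis, was at 35.1 ± 16 and 49.4 ± 25.4 CPM, and the filament gene Prph at 256 ± 91.7 and 367 ± 200 CPM. Schwann cell markers lay lower, and none passed by itself. Their median was -0.51 over 7 genes (camera adjusted p = 4.0e-04; adjusted p = 0.565 with an estimated correlation). That call ended without wild-type batch 1 (median -0.16). Sema3c, a ligand of Plxnd1 that motor neurons expressed at 145 ± 78.0 CPM in wild type and 181 ± 88.7 CPM in the knockout, was higher in 3 of 3 batches (paired 0.35 ± 0.06) and did not pass. Sema3e was at 5.50 ± 0.675 and 7.38 ± 1.69 CPM, and the co-receptors Nrp1 and Nrp2 at unpaired changes of 0.14 ± 0.15 and 0.24 ± 0.21; none passed.

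Unpaired edgeR called 0 genes higher and 2 lower of 16695, with 190 at an unadjusted p under 0.05 and 835 expected by chance. Both were processed pseudogenes. Gm13394 had 1031 counts over the 3 wild-type libraries and 3 over the knockout ones, a ratio of 379 (95 % counting interval 129 to 1840; edgeR adjusted p = 0.0277), and Gm5514 had 341 and 42 counts, a ratio of 8.95 (6.48 to 12.6; adjusted p = 0.0199). In endothelial cells their ratios were 157 (79.2 to 364) and 7.84 (5.15 to 12.4), with 2 wild-type libraries. Gm13394 is 99.9 % identical over 1000 bases to Gapdh, and Gm5514 is 98 % identical over 1002 bases to Ldhb, so reads can be divided between each pair; Gapdh, Ldhb and Rn7sk were chosen after their values were seen. Mean Gapdh was at 22 CPM in wild-type and 32.8 CPM in knockout motor neurons, while the sum of Gapdh and Gm13394 was 36.8 and 32.9 CPM. Ldhb did not show such a move, at 159 ± 16.8 and 150 ± 14.5 CPM, and Gm5514 is small beside it. The paired fit called 2 genes higher and 4 lower, adding the cell adhesion gene Cntn4 (38.8 ± 4.47 to 18.2 ± 4.06 CPM, -1.11 ± 0.12), which also lies on chromosome 6, and Plxnd1 on the lower side. DESeq2 called the same 4 lower and none higher. The higher genes, Alb and the noncoding RNA gene Rn7sk, came from knockout batch 1, which had 462 CPM of Alb, an albumin gene of liver, against at most 0.489 CPM in any other motor neuron library. Leaving that library out of the paired fit gave 104 genes (58 higher, 46 lower), a choice made after its values were seen; without pairing, leaving out wild-type batch 1, 2 or 3 gave 1 gene each and leaving out any knockout library gave 0. In edgeR the call of Gm5514 ended without any 1 library (adjusted p = 0.0578 to 0.233) and that of Gm13394 without wild-type batch 2 or any knockout library (0.0669 to 0.552).

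**Figure D3:**
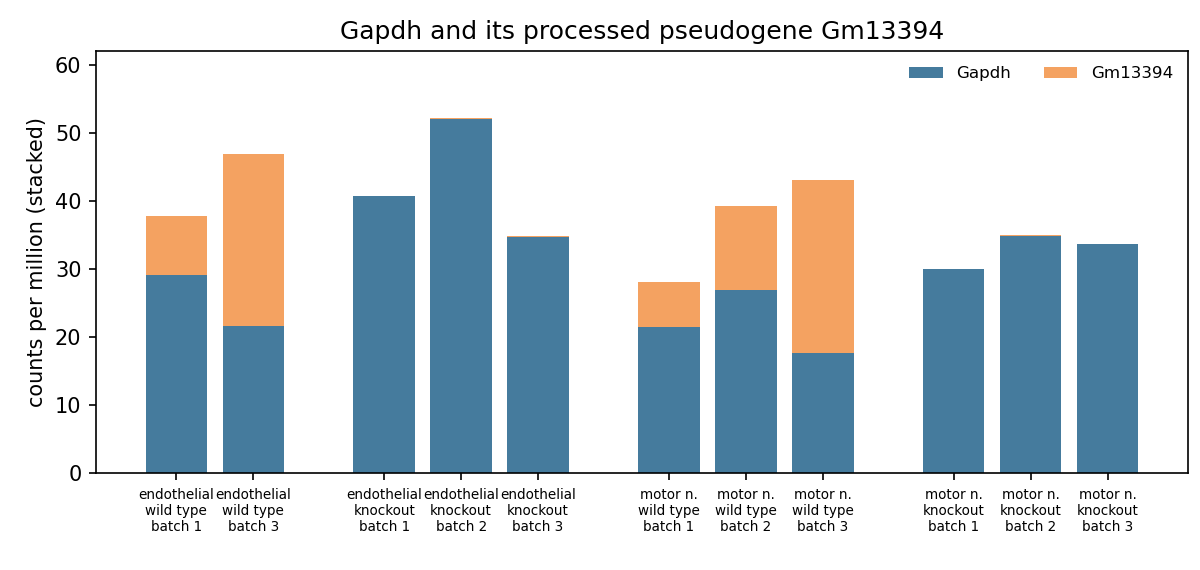
Stacked bars of Gapdh and of its processed pseudogene Gm13394 in CPM, one bar per library of the knockout series, ordered by group and batch. Gm13394 takes 6.68 to 25.4 in the wild-type libraries and at most 0.146 in the knockout libraries.

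Whether the effect of the knockout differed between the cell types was tested as an interaction. No member of a list passed by itself without pairing. Camera at a preset correlation called 6 lists, 3 on each side, and none with an estimated correlation (smallest adjusted p = 0.858). For the 21 proliferation genes the median difference of log2 fold changes was 0.34, all 21 being above 0 (camera adjusted p = 3.6e-07), for 7 Schwann cell markers it was 1.06 (adjusted p = 3.0e-06), and for 22 barrier genes -0.33 (adjusted p = 0.00148). The others were glycolysis and hypoxia (0.19), endothelial markers (-0.44) and neuronal genes (-0.37), with camera adjusted p = 0.0325, 0.0325 and 0.0429. Endothelial markers were low in wild-type motor neurons (Kdr 3.84 ± 1.40 and Flt1 1.21 ± 0.529 CPM). Their motor neuron pairs disagreed, at -0.312, -0.299 and 0.744 in batches 1 to 3. Marker lists of another cell type can thus read RNA of other cells in a library, which cannot be told apart here from an effect of the knockout. On the motor neuron side the pairs disagreed on proliferation, at -0.562 in batch 1 (0 of 21 genes higher), -0.031 in batch 2 and 0.162 in batch 3 (16 of 21), and the knockout library of batch 1 is the one with liver-type RNA. In the paired fit without that library the proliferation median was 0.052 and not called. The Schwann list was at 0.445 in the endothelial pair of batch 1 and -0.004 in that of batch 3. In the motor neuron pairs it was at -0.686, -0.308 and -0.049 in batches 1 to 3. The glycolysis call ended without endothelial wild-type batch 3 (0.18) or knockout batch 1 (0.11), or motor neuron wild-type batch 1 (0.18) or 2 (0.14) or knockout batch 3 (0.09). The endothelial call ended without endothelial wild-type batch 1 (-0.08) or knockout batch 2 (-0.23) or 3 (-0.46), or motor neuron wild-type batch 2 (-0.2) or 3 (-0.39) or knockout batch 3 (0.04). The neuronal call ended without endothelial knockout batch 1 (-0.27) or 2 (-0.17), or motor neuron wild-type batch 1 (-0.33) or 3 (-0.33) or knockout batch 2 (-0.27) or 3 (-0.44), and reversed without endothelial wild-type batch 3 (0.45). The barrier call ended without wild-type endothelial batch 1 (-0.09) or knockout motor neuron batch 3 (-0.28). Plxnd1 itself did not differ beyond the spread, at -0.23 ± 0.60. No single gene passed in unpaired edgeR (0 of 19266, with 352 at an unadjusted p under 0.05). DESeq2 called Prrt4, and the paired edgeR fit called 5: the cartilage collagen Col9a3 (1.22 ± 0.14), the adhesion gene Tenm3 (0.94 ± 0.11) and Prrt4 (1.83 ± 0.22) higher in endothelial cells, and Adh1 and Apob lower. Without knockout motor neuron batch 1, where Apob, a lipoprotein gene, was at 174 CPM, the paired fit called 0; without wild-type motor neuron batch 2 the unpaired fit called 1.

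Changes shared by the cell types were few at the main thresholds. No gene was called in both without pairing; with pairing Plxnd1, Gm13394 and Gm5514 were called lower in both (0.008 expected from independent lists). Rn7sk was called higher in both, from 1 library each: it was at 50.4 CPM in knockout endothelial batch 3 and 159.8 CPM in knockout motor neuron batch 1, and at most 1.27 CPM in the other libraries of the knockout series. At an unadjusted p under 0.01 without pairing, Eno1 was higher in both (0.026 expected) and Plxnd1, Cntn4, Gm13394 and Gm5514 lower (0.007 expected). Across 15938 genes, which are not independent replicates, the log2 fold changes of the cell types correlated at r = 0.187. Both cell types of a batch can come from the same pooled embryos, and their libraries of the same batch correlated (r = 0.11 to 0.275), so neither these expectations nor the r of 0.187 can single out a shared effect of the knockout. A knockout allele can carry linked variants, so calls within 20 Mb of Plxnd1 were counted. At an unadjusted p under 0.01 without pairing there were 5 such genes among 77 in endothelial cells (1.25 expected, Fisher exact p = 0.00825) and 4 among 21 in motor neurons (0.32 expected, p = 2.5e-04). Plxnd1 itself was not counted. Within 5 Mb there were 1 (0.46 expected) and 0 (0.13 expected) such genes, and with pairing 3 (3.57 expected) and 6 (1.52 expected, Fisher exact p = 0.00428). The counts within 5 Mb are too small to decide. Within 20 Mb at the same unadjusted threshold with pairing there were 22 in endothelial cells (9.75 expected, Fisher exact p = 3.9e-04). In motor neurons there were 14 (3.8 expected, Fisher exact p = 3.0e-05). Past the adjusted threshold of edgeR there were 0 in both without pairing, 431 and 190 genes having an unadjusted p under 0.05. With pairing there were 9 among 179 in endothelial cells (2.9 expected, Fisher exact p = 0.00263) and 1 among 5, Cntn4, in motor neurons (0.08 expected).

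Wild-type endothelial cells and motor neurons were compared to check the sort and to set ligand and receptor levels side by side. Kdr was at 215 ± 70.9 CPM in endothelial libraries (SD, n = 2) and 3.84 ± 1.40 CPM in motor neurons (n = 3), a log2 fold change of 5.78 ± 0.54, while Isl1 was at 31.2 ± 20.5 and 196 ± 72.3 CPM (-2.68 ± 0.50) and Mnx1, a motor neuron factor, at 0.704 ± 0.009 and 83.1 ± 44.8 CPM (-6.90 ± 0.77). Of 19266 genes, edgeR called 6517 higher and 5967 lower in endothelial libraries. All 20 endothelial markers were higher, such as Egfl7 (5.01), Emcn (5.85) and Flt1 (5.38), and 13 of 16 motor neuron markers were lower, such as Lhx3 (-5.51), Chat (-6.08) and the acetylcholine transporter Slc18a3 (-6.41). All 15 neuronal genes were lower, Nefl (-4.30) and Gap43 (-3.23) among them. Endothelial libraries also held mural, fibroblast, macrophage and red cell RNA above the motor neuron level: all 11 mural, all 15 macrophage and all 13 erythroid markers were higher, and 14 of 15 fibroblast markers. Examples were Pdgfrb of pericytes (468 ± 49.2 CPM), Col6a1 (658 ± 8.22 CPM), the macrophage receptor Mrc1 (248 ± 16.5 CPM) and embryonic haemoglobin Hba-x (1888 ± 603 CPM). Motor neuron libraries held interneuron RNA, with 11 of 14 markers lower in endothelial libraries, such as Gad2 at 366 ± 25.6 CPM in motor neurons. Lhx1, at 925 ± 116 CPM there, also stands on the fixed list of motor neuron subtype genes, so its level does not mark interneurons.

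Plxnd1 was at 196 ± 24.7 CPM in endothelial cells and 8.31 ± 3.52 CPM in motor neurons (4.53 ± 0.40; edgeR adjusted p = 4.4e-06). Sema3c was at 96.3 ± 4.74 and 145 ± 78.0 CPM, Sema3a at 31.0 ± 5.89 and 34.2 ± 7.40 CPM and Nrp1 at 169 ± 2.55 and 160 ± 26.1 CPM, differences that did not pass. Sema3g (2.41 ± 0.27) and Vegfa (0.84 ± 0.13) were higher in endothelial libraries and Nrp2 (-1.56 ± 0.25) in motor neurons. Sema3e was higher in endothelial libraries (0.91 ± 0.32; edgeR adjusted p = 0.0270), a call that ended without wild-type endothelial batch 1 or 3 or wild-type motor neuron batch 1 (adjusted p = 0.0921, 0.0816 and 0.0735). All 21 proliferation genes, 21 of 22 barrier genes, all 9 Notch targets and 13 of 14 basement membrane genes, such as Col4a1 (6.17) and Col4a2 (5.79), were higher in endothelial libraries. The arterial genes Dll4 (3.43) and Unc5b (2.41), the tip cell gene Esm1 (4.61) and Plvap of fenestrated vessels (5.32) were higher too, as were 13 of 14 immediate early and stress genes, such as Egr1 (4.88 ± 0.45), which rise during tissue dissociation.

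The regional comparison asked how endothelial cells inside the cord differ from those of the meninges. Spinal libraries had more endothelial, barrier, Notch and neural RNA, and meningeal libraries more fibroblast RNA, of 7755 genes called by edgeR (4019 higher and 3736 lower in spinal libraries, of 16213). Mfsd2a, a lipid transporter of the blood-brain barrier, was at 317 ± 71.1 CPM in spinal and 14.1 ± 4.91 CPM in meningeal libraries (SD, n = 5 each), a log2 fold change of 4.49 ± 0.25 (SE). Kdr was at 746 ± 202 and 263 ± 99.9 CPM (1.5 ± 0.26), and the collagen gene Col1a2 at 370 ± 160 and 4698 ± 1015 CPM (-3.67 ± 0.30). All 3 had the same direction in 5 of 5 batches.

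Of 22 barrier genes 16 rose, 3 fell (Slco1a4, Adgra2 and Reck) and 3 did not pass, with a median of 1.7 (camera adjusted p = 2.1e-06; adjusted p = 0.469 with an estimated correlation). The call of Adgra2 ended without spinal batch 3 or 5 or meningeal batch 3, 4 or 5 (log2 fold changes -0.47 to -0.37). Besides Mfsd2a, those that rose included Slco1c1 (3.24 ± 0.30), the proteoglycan gene Spock2 (165 ± 41.3 to 1518 ± 410 CPM), the transcription factor gene Foxq1 (2.73 ± 0.23) and Slc2a1 (251 ± 79.5 to 1187 ± 310 CPM). Of these 16, Spock2 alone was not called higher in endothelial cells than in motor neurons, so neuronal RNA stays open for it. The list of 13 Wnt targets went the other way, with pair medians from -0.928 to -0.254 and 2 to 5 genes higher per pair. Camera called it lower at the preset correlation, a call that ended with pairing. Of 20 endothelial markers 16 rose and 4 did not pass, with a median of 1.5 (camera adjusted p = 7.7e-06; adjusted p = 0.469 with an estimated correlation), such as Flt1 (57.0 ± 18.1 to 301 ± 78.7 CPM) and Ets1 (1.57 ± 0.20). Of 9 Notch targets 7 rose and 2 did not pass (median 1.24; camera adjusted p = 2.0e-06; adjusted p = 0.196 with an estimated correlation): Hey1 (9.96 ± 1.90 to 81.2 ± 7.35 CPM), the Notch ligand gene Dll4 (2.52 ± 0.26) and Nrarp (2.31 ± 0.19). Of 18 tip cell genes 12 rose and 3 fell (camera adjusted p = 1.9e-04), and of 18 arterial genes 12 rose and 4 fell (adjusted p = 8.2e-05; adjusted p = 0.469 with an estimated correlation for both): the chemokine receptor Cxcr4 (7.99 ± 2.37 to 115 ± 10.5 CPM) and Unc5b (2.57 ± 0.20) belong to both, and Apln (2.59 ± 0.23) and Esm1 (1.02 ± 0.21) to the first. Of 13 genes of fenestrated or peripheral vessels 2 rose, 7 fell and 4 did not pass (median -0.66; camera adjusted p = 0.0177; adjusted p = 0.469 with an estimated correlation), the water channel Aqp1 (-4.00 ± 0.27) and Meox2 (-3.04 ± 0.20) among the lower. That list's call ended without spinal batch 3 (-0.79, camera adjusted p = 0.061). Plvap, of the same list, did not pass (0.44 ± 0.22; edgeR adjusted p = 0.122) but did without spinal batch 3 (0.56, adjusted p = 0.0337) or meningeal batch 4 (0.62, adjusted p = 0.0304).

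**Figure D4:**
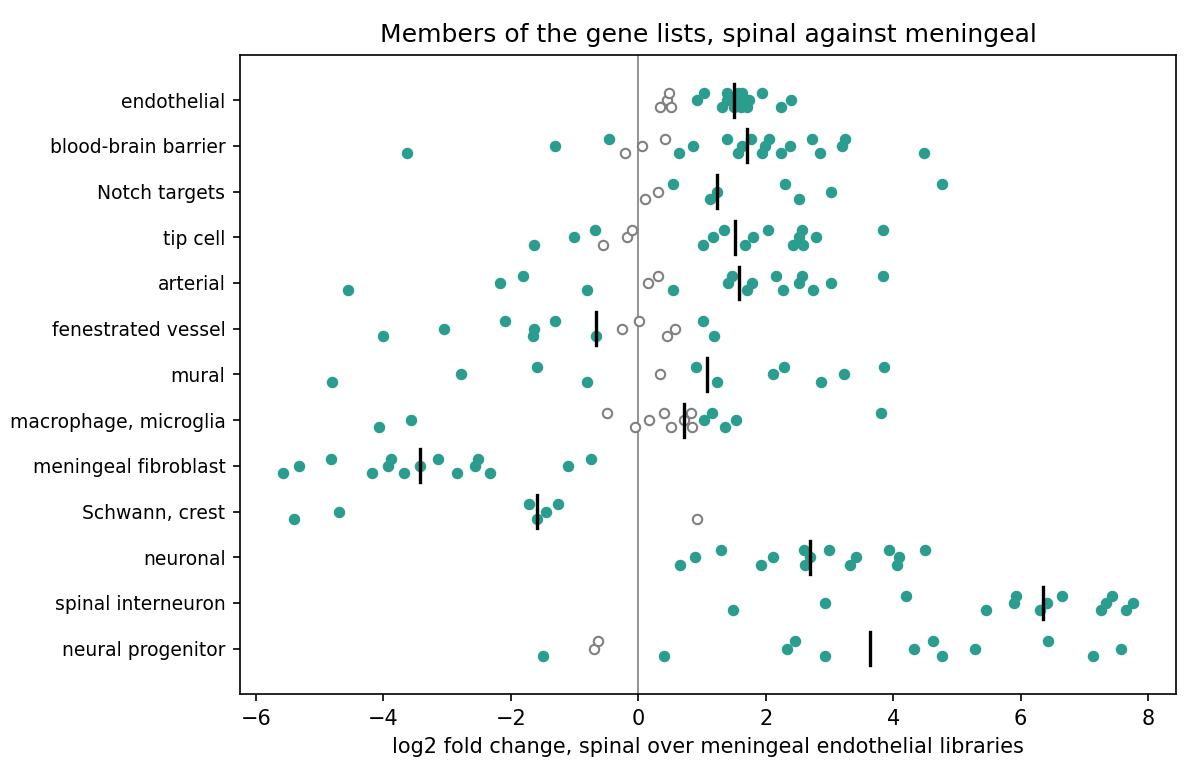
Log2 fold changes of spinal over meningeal endothelial libraries (n = 5 each) for the members of 13 gene lists; filled circles passed an edgeR adjusted p of 0.05, open ones did not, and the black bar is the median. Fibroblast markers all lie below 0 and spinal interneuron markers all above 0, with medians of -3.43 and 6.36.

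Markers of other cells differed as strongly. All 15 meningeal fibroblast genes were lower in spinal libraries (median -3.43; camera adjusted p = 2.4e-14; adjusted p = 0.14 with an estimated correlation), such as Col1a1 (3034 ± 513 to 517 ± 119 CPM) and Col6a1 (-3.43 ± 0.23). All 15 neuronal and all 14 spinal interneuron genes were higher (medians 2.69 and 6.36), as were 11 of 14 neural progenitor genes (median 3.63). Examples were Map2 (27 ± 4.88 to 464 ± 134 CPM), Dcx (4.49 ± 0.37), Lhx1 (0.171 ± 0.130 to 31.2 ± 12.3 CPM), Gad1 (5.46 ± 0.37) and Sox2 (4.62 ± 0.32). Lhx1 also stands on the list of motor neuron subtype genes. Olig2, of the motor neuron list, was higher as well (8.23 ± 0.72). Wnt7b (0.496 ± 0.422 to 99.6 ± 43.5 CPM), Ntn1 (5.17 ± 0.28) and Slit1 (5.36 ± 0.35) were higher too, but the list of other guidance genes went both ways: of 29 members 14 rose, 9 fell and 6 did not pass (median 0.22; camera adjusted p = 0.61), with pair medians from -0.195 to 0.813. Macrophage genes divided, with the microglial receptor P2ry12 higher (14.9 ± 4.04 to 210 ± 80.4 CPM) and Mrc1 (703 ± 229 to 59.7 ± 16.2 CPM) and Pf4 (-4.07 ± 0.34) of other macrophages lower; of 15 members 5 rose, 2 fell and 8 did not pass. Mural genes divided likewise, 7 higher and 4 lower of 12: Abcc9 (3.23 ± 0.28) and Cspg4 (2.87 ± 0.20) of pericytes were higher, and the smooth muscle genes Acta2 (148 ± 14.7 to 5.36 ± 2.43 CPM) and Tagln (-2.78 ± 0.13) lower. Lyve1, of lymphatic vessels and some macrophages, was at 7.38 ± 7.73 CPM in spinal and 268 ± 85.4 CPM in meningeal libraries.

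Among semaphorins and plexins 14 of 31 were higher and 6 lower in spinal libraries. Plxnd1 was higher (0.66 ± 0.22; edgeR adjusted p = 0.0295; 5.2e-04 to 0.49 over the alternatives) in 5 of 5 batches, a call that ended without spinal batch 1, 4 or 5 or meningeal batch 1, 2, 3 or 5 (adjusted p = 0.051 to 0.0827). Its ligands Sema3e (10.8 ± 1.36 to 1.43 ± 0.402 CPM; -2.92 ± 0.21) and Sema3c (73.6 ± 11.9 to 13.3 ± 7.55 CPM; -2.47 ± 0.30) were lower, and Sema3g (2.15 ± 0.30) and Sema6d (2.68 ± 0.23) higher. Vegfa was lower in spinal libraries (111 ± 12.9 to 31.8 ± 16.7 CPM, -1.81 ± 0.29). Endothelial markers outside the barrier list rose more than Plxnd1, by a median of 1.502 over 19 genes. A larger endothelial share in the spinal libraries could therefore raise Plxnd1 too. Meningeal libraries also held more fibroblast RNA, and whether Sema3e, Sema3c and Vegfa differ within endothelial cells was not tested. Nrp1 (0.15 ± 0.15), Nrp2 (-0.26 ± 0.15) and Sema3a (0.10 ± 0.34) did not pass; in the batches of whole cord alone Sema3a was lower, at -0.86 (edgeR adjusted p = 1.1e-04; 1.1e-04 to 1 over the alternatives). Its difference between ventral and whole cord did not pass in the dissection test (1.34 ± 0.38, edgeR adjusted p = 0.0986). Whole cord is tied to batches 4 and 5.

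The regional signatures were then read in the knockout libraries, to ask whether endothelial cells without Plxnd1 shift along the axis from meninges to cord. The 200 genes most clearly higher in spinal libraries, 199 of them tested, had a median log2 fold change of -0.09 in unpaired knockout endothelial cells (71 above 0; camera p = 0.183; p = 0.838 with an estimated correlation) and 0.11 with pairing (143 above 0; camera p = 2.0e-10; p = 0.319 with an estimated correlation). The direction hung on single libraries: the median was 0.54 without wild-type batch 3, 0.08 without knockout batch 2, -0.51 without wild-type batch 1 and -0.47 without knockout batch 3. Spinal libraries also held more neural RNA, so this set can read neural RNA as well as the state of endothelial cells. Over the same leave-outs the neuronal list ran from -0.794 to 0.452 and the interneuron list from -0.93 to 0.458. The knockout series was sorted from cord with meninges, so a different mix of the 2 sources cannot be told apart from a shift. The 200 meningeal genes had a median of 0.01, which camera did not call. It did so without wild-type batch 1 (median 0.06) and without knockout batch 1 (0.02). Across 15824 genes, which are not independent replicates, the correlation of the knockout and regional fold changes was -0.119 without pairing and 0.094 with it.

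The spinal batches differ in dissection, so the dependence of the regional difference on ventral against whole cord was tested, with the meninges of the same batches as reference. Among the genes that passed, 4 of 15 fibroblast genes were higher in ventral than in whole cord relative to those meninges. Lower were 9 genes whose names start with Rpl or Rps and a number, as those of ribosomal protein genes do. This group was formed after the result was seen and was not tested as a list. Col1a2 was at 470 ± 118 CPM in ventral (n = 3) and 219 ± 10.3 CPM in whole cord libraries (n = 2), against 3966 ± 218 and 5798 ± 14.7 CPM in the meninges of the same batches (ventral minus whole 1.62 ± 0.28). Nkx6-1, a homeobox gene, was at 59.8 ± 11.3 and 22.2 ± 0.153 CPM (1.68 ± 0.21), with higher levels in the meninges (66.4 ± 4.55 and 80.5 ± 4.37 CPM), and the neuropeptide gene Npy at 3.62 ± 0.708 and 22.5 ± 1.17 CPM (-3.56 ± 0.40). The fibroblast genes that passed were Col3a1 (1.56 ± 0.24), Col6a1 (1.19 ± 0.20) and Tbx18 (1.26 ± 0.23) besides Col1a2; 11 did not pass, and the median was 1.54 (camera adjusted p = 5.7e-11; adjusted p = 0.0915 with an estimated correlation). The laminin gene Lama2 (1.69 ± 0.28), Ccn4 (2.13 ± 0.18), Fibin (2.35 ± 0.43) and the hydroxylase gene Cyp7b1 (2.23 ± 0.33) were higher too. In all, 98 genes passed, 25 higher and 73 lower of 17901. The 9 genes with such names included the ribosomal protein genes Rps27 (-1.66 ± 0.29), Rpl41 (-1.51 ± 0.23), Rps14 (-1.5 ± 0.22) and Rpl36 (-1.45 ± 0.19). The chemokine gene Ccl9 was lower too (-2.12 ± 0.35). Both tissues contributed: Rps27 was at 202 ± 34.3 CPM in ventral and 366 ± 22.4 CPM in whole cord, and at 832 ± 201 and 490 ± 5.76 CPM in the meninges of those batches. A stricter rule on such names, which can still take S6 kinase genes, gave 93 tested genes. Their median was -0.98, and 85 lay below 0. Mfsd2a (0.32 ± 0.35) and Plxnd1 (0.28 ± 0.34) did not pass. The dissection is tied to the batch numbers, and the count rested on single libraries, at 1, 1190, 107, 0 and 0 genes without spinal batch 1, 2, 3, 4 or 5 and 582, 2, 37, 1 and 0 without meningeal batch 1, 2, 3, 4 or 5.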

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

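No test in this part was chosen after its result was seen. A library was set apart where its gap to the nearest of 5 libraries in its group was too large a part of their range by Dixon's test, applied to the regional groups only, since the others hold 2 or 3. This marked 10 of 142 groups of values, where chance gives about 1 in 20, or 7.1. In spinal libraries these were the interneuron gene Gad1 at 37.8 CPM in batch 3 (14.3 to 16.6 in the others), the macrophage gene Mrc1 at 87.9 in batch 1 (47.2 to 57.2), the pericyte gene Abcc9 at 2467 in batch 2 (905 to 1229), the choroid plexus gene Ttr at 0.195 in batch 4 (0 to 0.0549) and the organic anion transporter Slc22a6 at 6.79 in batch 1 (0 to 0.361). In meningeal libraries they were Sema6d at 184.9 CPM in batch 4 (138 to 146), Ttr at 78.5 in batch 3 (3.73 to 12.6), Slc22a6 at 116.8 in batch 5 (88.5 to 96.4), Ntn1 at 6.07 in batch 2 (9.60 to 10.1) and Ccn4 at 78.9 in batch 5 (72.1 to 73.4). No library carried more than 2 of the 10, and no explanation was tested.

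A second group of results differed between the dissections: the spinal minus meningeal difference depended on ventral against whole cord for 98 genes in the edgeR interaction test. The genes named in the report were Npy (-3.56), Ccl9 (-2.12), Rps27 (-1.66), Rpl41 (-1.51), Rps14 (-1.5), Rpl36 (-1.45), Fibin (2.35), Cyp7b1 (2.23), Ccn4 (2.13), Lama2 (1.69), Nkx6-1 (1.68), Col1a2 (1.62), Col3a1 (1.56), Tbx18 (1.26) and Col6a1 (1.19). The ventral libraries are batches 1 to 3 and the whole cord ones batches 4 and 5, so tissue and batch cannot be told apart here. The count was 0 without spinal batch 4 or 5 or meningeal batch 5, 1 without spinal batch 1 or meningeal batch 4, 2 without meningeal batch 2, 37 without meningeal batch 3, 107 without spinal batch 3, 582 without meningeal batch 1 and 1190 without spinal batch 2. Without spinal or meningeal batch 4 or 5, the whole cord or its meninges are left with 1 library, which is assumed to vary like the others.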

How the results depend on the processing

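Alternatives chosen after seeing the data were all files as deposited, the paired fits without Y genes and Xist, without knockout motor neurons of batch 1 or with regional numbers 1 and 2 crossed, and pairing in the overlap and in the calls near Plxnd1. Of 4253 values recomputed under the alternatives, 3820 kept their side of the threshold, 37 of them uncalled values that changed sign, 270 fell below it, 147 passed it newly and 16 reversed. Unless a sentence says otherwise, the cause was not tested. Genes differing between endothelial cells and motor neurons numbered 8410 to 13327, and between spinal and meningeal cells 6101 to 8793, except for glmTreat with 3678, which asks for a minimum fold, and 7134 to 7904 without 1 library.
The endothelial knockout count, 0, was 2 with no filter, 34 with DESeq2, 180 with pairing, 55 with DESeq2 and pairing, 1 and 15 in the fit of all knockout-series libraries without and with pairing, 177 with pairing and no Y genes or Xist, 0 as deposited with and without pairing, and 0 to 1 without 1 library (1 without wild-type batch 1). The motor neuron count, 2, was 4 with no filter, 0 with the strict filter, 4 with DESeq2, 6 with pairing, 35 with DESeq2 and pairing, 1 and 10 in the fit of all libraries, 104 with pairing and no knockout batch 1, and 0 to 1 without 1 library (0 without any knockout library, 1 without any wild-type one). The interaction count, 0, was 1 with DESeq2, 5 with pairing and 0 to 1 without 1 library (1 without wild-type motor neurons of batch 2). The dissection count, 98, was 305 with RLE scaling, 1780 with no filter, 236 with the strict filter, 1321 with DESeq2, 2 with glmTreat and 0 to 1190 without 1 library (values for each library are given above). Shared knockout calls, 0, were 5 at an unadjusted p, 4 with pairing and 38 with both. Calls near Plxnd1, 0 in both cell types, were 5 and 4 at an unadjusted p and 9 and 1 with pairing.
The spinal signature's median in the knockout, -0.088, was 0.108 with pairing and -0.508 to 0.54 without 1 library: it reversed without wild-type batch 3 (0.54) or knockout batch 2 (0.084), and was -0.508 without wild-type batch 1 and -0.467 without knockout batch 3. The meningeal one, 0.006, was 0.009 with 500 genes and -0.035 to 0.063 without 1 library. Without 1 library, medians of lists in the endothelial knockout ran from -0.794 to 0.452 (neuronal), -0.93 to 0.458 (interneuron), -0.626 to 0.018 (endothelial), -0.187 to 0.685 (lymphatic) and -0.399 to 0.958 (progenitor), reversing without wild-type batch 3 in the first 2 and batch 1 in the others. The interneuron list was also at 0.029 with pairing, 0.015 in the paired fit of all libraries and 0.029 without Y genes and Xist. In motor neurons they ran from -0.042 to 0.585 (motor neuron list, reversed without knockout batch 2) and -0.418 to 0.091 (proliferation, reversed without wild-type batch 1, and 0.033 with pairing and no knockout batch 1). In the interaction they ran from -0.929 to 0.452 (neuronal, reversed without wild-type endothelial batch 3) and -0.858 to 0.044 (endothelial, reversed without knockout motor neurons of batch 3). Sema3a, spinal minus meningeal, reversed to -0.86 in the whole cord batches. Where an arm keeps 1 library, as for wild-type endothelial cells, it is assumed to vary like the others. Pairing ended the calls of Adgra2 (-0.45) and of the Wnt target list (-0.444) between spinal and meningeal libraries, and of the neuronal list in the endothelial knockout (-0.034) and in the interaction (-0.067). Lists called by camera went from 13 to 18 in the endothelial knockout, 8 to 10 in motor neurons, 6 to 19 in the interaction and 25 to 26 between cell types with pairing, and numbered 16 both ways between spinal and meningeal libraries. Lists not called without pairing were not followed under the other alternatives.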

Other observations

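The test of reads shared by Gm13394 and Gapdh, the tests of the glycolysis list on other cell types, on the endothelial share and on members without copies, and both tests of the barrier list were chosen after the result was seen. The others in this part were set down before their results were seen, but the use of paired fits for genes near Plxnd1 was chosen after the data were seen. Genes named only here were chosen after their values were seen.

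Several lists of the knockout series are described only here. The 21 proliferation genes were all above 0 in knockout endothelial cells (median 0.178; camera adjusted p = 8.9e-07; adjusted p = 0.802 with an estimated correlation) and all below 0 in knockout motor neurons (-0.181; camera adjusted p = 0.00112; adjusted p = 0.901 with an estimated correlation), and none passed by itself. The motor neuron pairs disagreed, with medians of -0.562, -0.031 and 0.162 in batches 1 to 3. The first call ended without wild-type endothelial batch 3 (0.048), the second without wild-type motor neuron batch 1 (0.091) or knockout motor neuron batch 2 (-0.017). The Schwann cell list was at 0.547 in endothelial cells (camera adjusted p = 9.2e-04, and adjusted p = 0.802 with an estimated correlation), a call that ended without wild-type batch 1 (0.124). Its pairs disagreed, at 0.445 in batch 1 (7 of 7 genes higher) and -0.004 in batch 3 (3 of 7). In the dissection test, the spinal minus meningeal difference of the erythroid and macrophage lists was lower with ventral than with whole cord, by medians of -2.631 and -0.977 (camera adjusted p = 3.1e-06 and 2.4e-06; adjusted p = 0.778 with an estimated correlation for both), and no member passed by itself. The ventral batches disagreed: the erythroid difference was -3.161, 2.074 and -0.428 in batches 1 to 3, against 2.544 and 2.049 with whole cord, and the macrophage one -0.573, 0.514 and 0.266, against 1.05 and 1.309.

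The knockout motor neuron library of batch 1 held RNA of liver type: Alb was at 462 CPM, Apob at 174 and Apoa2 at 42.6, where the other motor neuron libraries had 0.269 to 0.489 CPM of Alb. It also held 4834 CPM of Mir6236, 3526 of Lars2, 1149 of Gm42418 and 159.8 of Rn7sk, and 1.52 % mitochondrial counts, against 0.87 to 0.943 % in the other motor neuron libraries. Lars2 does not mark that library alone: it was at 143.4 to 168.2 CPM in the knockout endothelial libraries, against 73.7 and 83.6 CPM in wild type. Whether the other endothelial differences, glycolysis included, go with it was not tested.

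Gm13394 and Gm5514 lost most of their counts in knockout cells of both types, and their parent genes Gapdh and Ldhb lie on chromosome 6, as Plxnd1 does. Reads shared between pseudogene and parent may explain Gm13394. With the counts of Gapdh added, knockout and wild-type means differed by at most 0.504 SD of the wild-type libraries. Wild-type and knockout means of this sum were 42.4 and 42.6 CPM in endothelial cells and 36.8 and 32.9 in motor neurons. The pairs disagreed. In batch 3 the sum fell from 46.96 to 34.9 CPM in endothelial cells and from 43.06 to 33.68 in motor neurons. In batch 1 it rose from 37.8 to 40.77 and from 28.1 to 30.03 CPM. In motor neuron batch 2 it fell from 39.25 to 34.93 CPM. Knockout endothelial batch 2, at 52.26 CPM, has no partner. A full move of reads to Gapdh is therefore not settled. A variant near Plxnd1, carried along with the knockout allele from another strain, is a candidate explanation for such a move of reads. Gm5514 has too few counts beside Ldhb (150.2 to 163.8 CPM for the sum in motor neurons) for this test. In the regional series, all wild type, Gm5514 ran from 0.1099 to 2.276 CPM in spinal and from 0.2475 to 3.188 CPM in meningeal libraries. Its level can therefore differ strongly without the knockout. Apart from Gm13394 and Gm5514, 15.4 % of 13 changed pseudogenes had a parent near Plxnd1, against 4.85 % of 516 others (Fisher exact p = 0.138), too few to decide. Genes 5 to 40 Mb from Plxnd1 at an unadjusted p under 0.01 in the paired fits numbered 30 in endothelial cells (14.65 expected, Fisher exact p = 2.2e-04) and 10 in motor neurons (5.65 expected, Fisher exact p = 0.0799), an excess past 0.05 in the first alone. Linked variants and regulation by Plxnd1 cannot be told apart for these genes, since strain backgrounds are not in the sources used here.

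The glycolysis and hypoxia list had a median of 0.342 in knockout endothelial libraries in the paired fit, and the technical explanations could be excluded for part of it only. Reads shared with processed copies are argued against for the 11 members without a copy, whose median was 0.342 (SE 0.0841 over members; 9 above 0, 1 of which passed). For the 8 members with copies they stay open. Adding the counts of 39 copies left the list at 0.342, but this moved almost nothing, since the copies held 0.936 % of their parents' counts in wild type and 0.716 % in the knockout, and reads with several alignments are not in the counts. Leaving out the 2 members on chromosome 6 also left 0.342, an outcome that the other 17 members had fixed. Of the 5 that rose, 4 lie on other chromosomes, so a variant near Plxnd1 acting on its neighbours alone would not reach them, while one acting through another gene stays open. RNA of other cell types stays open as well. In the paired fit the macrophage and erythroid lists had medians of -0.129 and -0.216, but the pairs disagreed: the macrophage list was at 0.076 in batch 1 and -0.364 in batch 3, and the erythroid list at -0.421 and -0.023. A lower endothelial share would raise all other cell types alike. The cartilage and Schwann lists lay above those lists by 0.823 (SE 0.167 over members) in batch 1 and 0.446 (SE 0.24) in batch 3, the second less than 2 SE, so a lower share is not excluded. The endothelial list was at -0.246 in batch 1 and 0.049 in batch 3, so the fall that a lower share would bring was seen in 1 pair only. The neuronal list was at 0.092 and -0.248 in these pairs. Stage was not tested. In the same fit 4 of the 5 genes of the sex-linked list fell, though Ddx3y and Kdm5d were higher in 1 of 2 pairs. In wild type the SD of Y-linked genes was above their mean (Ddx3y 43.1 ± 61.0 and Eif2s3y 50.2 ± 70.9 CPM, n = 2). The wild-type pools therefore differed strongly in Y-linked RNA, so their mix of sexes was uneven. Whether the mix of sexes bears on the glycolysis list was not tested and stays open too.

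The barrier list was higher in spinal than in meningeal endothelial libraries, and a larger endothelial share in the spinal libraries could raise it. Over the members not shared by both lists, the barrier median was 1.765 (21 genes) and the endothelial one 1.502 (19 genes), a difference of 0.263 (permutation p = 0.154 over genes). The 2 explanations cannot be told apart for the list as a whole. Abcb1a, Foxq1, Mfsd2a, Slco1c1 and Spock2 lay above Flt1, the highest endothelial marker at 2.40. RNA of motor neurons is argued against, since 93.75 % of the 16 barrier genes called higher in spinal libraries were called higher in endothelial cells than in motor neurons, all but Spock2. Other neural cells were not tested.

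Other splits of the same libraries were counted. For spinal against meningeal libraries, chance can be excluded: of 100 splits drawn from 126, only the real one gave as many genes (1 split), with 7755 genes against at most 1 in the others. With pairing there are 16 splits, too few for a share under 0.05; the real one gave 7336 genes and the highest other 0. For the motor neuron knockout there are 10 splits, also too few, and 3 of them, the real one with its 2 genes included, gave at least as many. The highest other, 648 genes, set wild-type batches 1 and 3 and knockout batch 3 against the rest, which points to a structure of the samples other than genotype, while the 3 other splits that part every pair gave 0. With pairing there are 4 splits, again too few, and only 1, the real one, gave as many genes, with 6 against at most 2.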
